A study of Mus musculus with 14 samples.

How the data were processed

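RNA of anterior cingulate cortex tissue was sequenced from 14 samples in 4 groups: AKR/J and C57BL/6NJ mice (AKR and B6N), naive (4 libraries each) or taken after observational fear conditioning (OFL, 3 libraries each). Per the labels, total RNA was extracted with Trizol and all libraries were made with the same TruSeq kit. The submitters' processing notes name CASAVA, cutadapt 2.7, TopHat2 2.1.1, HTSeq and edgeR with the genome build GRCm38, and they name no annotation release. The authors deposited a table of raw counts per Ensembl gene for the naive libraries and another for the OFL libraries, and these counts were the input here. The authors also deposited a table of CPM values for each sample, that is counts scaled to a library size multiplied by a factor between 0.9877 and 1.0175. Multiplying each CPM value by that size gave whole reads within 0.1 read for 100% of the values, and no gene differed from the count tables. The design had assumed that the sample tables held counts, so the planned comparison of the inputs became a comparison of the count tables with the reads recovered from the CPM values. All 14 columns of the count tables were used and none was left out.

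Gene names, positions and classes came from the GENCODE annotation of the mouse build GRCm38, which gave names to 53274 of the 53465 gene identifiers, and the other 191 were kept and counted without a name. Genes were named under their symbols. Counting that ignores strand cannot tell apart reads of genes that overlap an exon of the other strand. Whether each set was counted by strand is not known for certain. Reads of near-identical copies cannot be told apart in either case. The text marks values of copied genes as uncertain, but apart from Arnt2 it does not mark single genes for overlap with the other strand. Arnt2 has exonic bases under an exon of the other strand, a limit on its values in every comparison. Sequence shared between processed pseudogenes and their parents was counted as common stretches of 31 bases, with at least 20 stretches and 5% of the copy shared.

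Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes passed edgeR's expression filter by group, libraries were scaled by TMM, and the quasi-likelihood F-test was two-sided with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Strain differences (AKR minus B6N) were fitted within naive and within OFL libraries. The OFL minus naive differences in each strain, and the interaction (change in AKR minus change in B6N), came from 1 fit of all 14 libraries. Levels are TMM-scaled CPM with the standard deviation over libraries. The standard error (SE) of a log2 difference comes from the same fit. With total counts of 13487311 to 25780227 per library, the common biological coefficient of variation was 0.0446 in naive libraries, 0.0456 in OFL libraries and 0.0450 over all.

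The comparisons, the tests, 34 gene lists (cell types, stress and activity programs, receptors, and checks such as blood, choroid plexus, striatum and sex-linked genes) and the rule for named genes were chosen before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with a correlation estimated from the data and fry, and counts of members called over all genes or adjusted over the list alone. The rule named, for each comparison, Arnt2, Sst, Nrxn3 and Cacna1c, with Glo1, Soat1, Hc and Nnt in the strain comparisons. It added the 10 genes with the largest positive and the 10 with the largest negative log2 difference among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries. The overlap condition was not applied to the interaction, and genes known only by a predicted-gene number, a clone or pseudogene name or an identifier were counted but not named. From each list it took up to 4 called members with the smallest p, or, where none was called, the member with the smallest p as a value. Hc did not pass the expression filter. Not every gene that the rule allows is printed, and in the OFL minus naive comparisons the text names only some of the list members. Malat1, the histone genes as a class, Xist and the pseudogene pairs of the closing section were chosen after their values were seen.

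The tests were tried on simulated negative binomial counts with the measured library sizes and dispersions, and with means averaged over the groups. In these counts 200 genes with a mean count of at least 50 were changed. At 2-fold, between 98.5% and 100% of the changed genes were recovered, at 1.5-fold between 76.1% (interaction) and 94.0%, and between 1.53% and 9.26% of the calls were false. The highest false share, 9.26% in the naive comparison, was above the threshold of 0.05. The real fits called between 1044 and 15968 genes, and the simulation does not cover differences that widespread. The tests of genes were computed again with median-of-ratios and upper-quartile scaling, no count filter and a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom and a test against a fold of 1.5 (glmTreat). Other settings were a block by replicate number and each library left out in turn, both also used for the gene lists, all 14 libraries in 1 fit for the strain comparisons, the libraries of the contrast alone and quantile normalization for the OFL minus naive comparisons. Also tried, chosen after seeing the data, were the reads recovered from the CPM values, protein-coding genes that share no sequence with a tested pseudogene, protein-coding genes with no exonic base under an exon of the opposite strand, and naive libraries thinned to the mean depth of the OFL libraries (14090695 counts). Group labels were also exchanged between libraries in every split, or in a seeded draw of 90 splits for the interaction, to count how often as many genes were called. The replicate numbers of different groups did not pair the libraries: residuals of libraries with the same number correlated by 0.0439 at most. Figures and joins used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.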

Results

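Messenger RNA was counted by bulk RNA sequencing in the anterior cingulate cortex, a midline frontal region, of AKR/J mice (AKR) and C57BL/6NJ mice (B6N). Each strain gave 4 libraries from naive mice and 3 libraries from mice taken after observational fear conditioning (OFL in the labels), a procedure in which a mouse watches another mouse receive shocks. The series title concerns the transcription factor ARNT2 and somatostatin interneurons, the inhibitory neurons marked by the peptide gene Sst. Total counts per library were 19073921 to 23782061 in naive AKR, 20583264 to 25780227 in naive B6N, 13487311 to 14396289 in AKR after OFL and 14063573 to 14526253 in B6N after OFL. Between 25959 and 27316 genes had a count in a library. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The first principal component, with 85.4% of the variance, separated the OFL libraries from the naive ones, and the second, with 8.09%, separated the strains. Spearman correlations across genes were 0.994 to 0.997 between libraries of 1 group, 0.984 to 0.987 between strains within a condition, and 0.897 to 0.905 between conditions within a strain.

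The first comparison asked how the cortex of naive mice differs between the strains. Arnt2, which encodes a bHLH-PAS partner protein for neuronal and hypoxia-responsive transcription factors (ENSMUSG00000015709, chromosome 7, 84246278 to 84410176, minus strand, GRCm38), was higher in naive AKR, at 699.6 ± 16.6 CPM (counts scaled by library size; SD, n = 4) against 435.9 ± 3.30 (SD, n = 4) in naive B6N. The difference was 0.68 on the log2 scale (SE 0.03), a fold of 1.61 (edgeR adjusted p = 1.7e-11). Sst (ENSMUSG00000004366, chromosome 16, 23889573 to 23890958, minus strand) stood at 164 ± 7.37 CPM (SD, n = 4) in AKR and 155 ± 3.42 CPM (SD, n = 4) in B6N, and this difference did not pass the test (log2 0.08, SE 0.04, edgeR adjusted p = 0.10), although it did without AKR naive replicate 3 (adjusted p = 0.0232). Glo1, encoding the methylglyoxal-clearing enzyme glyoxalase, was higher in AKR by 0.92 (SE 0.04, edgeR adjusted p = 2.3e-12). Soat1, encoding an enzyme that esterifies cholesterol, was lower in AKR at -0.73 (SE 0.05, edgeR adjusted p = 4.9e-09). The L-type calcium channel gene Cacna1c was lower in naive AKR at -0.26 (SE 0.05, edgeR adjusted p = 0.00019), while Nrxn3, a presynaptic adhesion gene, had a difference of 0.02 (edgeR adjusted p = 0.70) and the mitochondrial transhydrogenase gene Nnt 0.01 (edgeR adjusted p = 0.90).

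**Figure D1:**
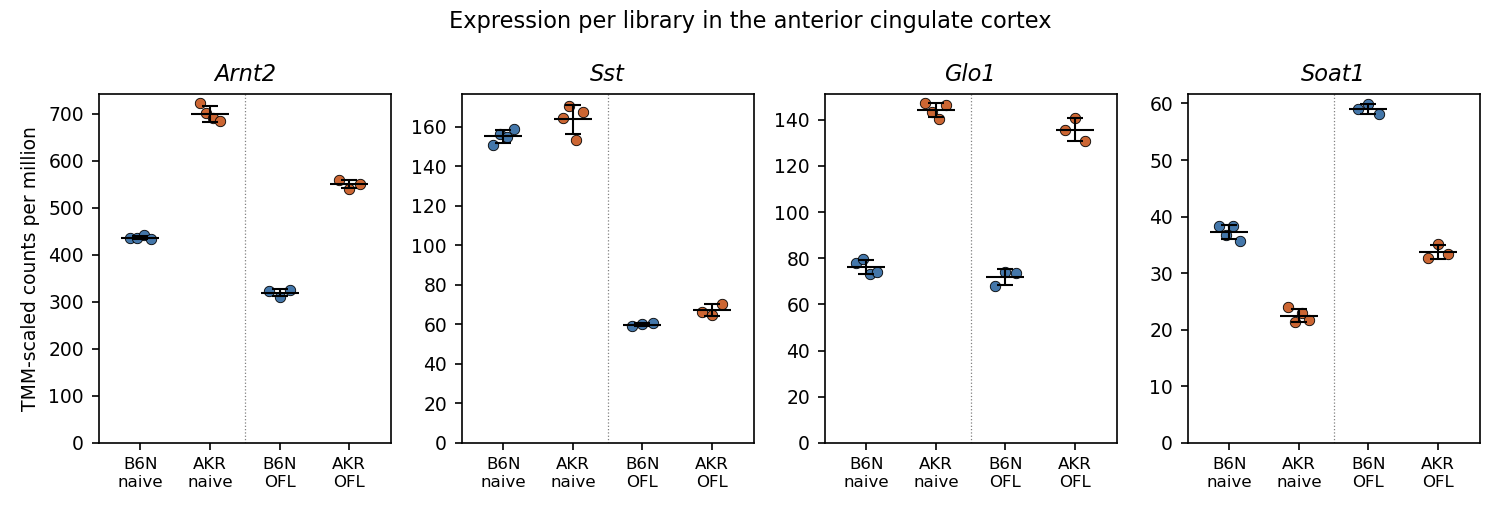
CPM of Arnt2, Sst, Glo1 and Soat1 in each library (points) of the 4 groups on the x axis, with the group mean and SD (bars; n = 4 naive, n = 3 OFL). Every AKR library lies above every B6N library of its condition for Arnt2 and Glo1 and below for Soat1, while the naive groups overlap for Sst.

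Among the named genes with the largest naive differences, the phospholipase gene Pla2g4e was at 70.2 ± 1.72 CPM (SD, n = 4) in AKR and 8.56 ± 1.48 in B6N (log2 3.03, SE 0.07). Tagap, encoding a GTPase-activating protein of T cells, was higher by 3.31 (SE 0.11), and the cilium gene Cfap54 by 1.98 (SE 0.06). Pttg1, encoding securin, a regulator of chromosome separation, was lower at -6.19 (SE 0.16), Myo7a, an unconventional myosin, at -3.52 (SE 0.07), and Kcnj16, an inward rectifier potassium channel of glia, at -3.20 (SE 0.08). Etnppl, an astrocyte enzyme of phosphoethanolamine breakdown, was lower at -3.05 (SE 0.09) and Fcrls, a microglial receptor gene, at -2.63. Tuba1c (5.65), Hmga1b (5.69), Vcp-rs (5.17), Eno1b (4.66) and Rps3a2 (4.14) were also higher in AKR, but each has close relatives elsewhere in the genome, so these values are uncertain.

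Glucocorticoid response genes, those induced by stress hormones, were lower in naive AKR as a group. Of 17 tested, 15 were lower and none higher (16 lower adjusted over the list alone), with a median of -0.63 (camera adjusted p = 3.78e-14; adjusted p = 0.280 with an estimated correlation). Fkbp5, encoding a cochaperone of the glucocorticoid receptor, was at 33.2 ± 1.92 CPM (SD, n = 4) in AKR and 73.0 ± 10.1 in B6N, a difference of -1.14 (SE 0.08). Tsc22d3, encoding a leucine zipper protein induced by glucocorticoids, was also lower at -1.14 (SE 0.04), the kinase gene Map3k6 at -2.04 (SE 0.10) and the lipid droplet gene Plin4 at -1.70 (SE 0.13). Of 11 heat shock and chaperone genes, 9 were lower (10 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 3.52e-05; adjusted p = 0.83 with an estimated correlation). Hspa5 (-0.82, SE 0.07) and Hsph1 (-0.55, SE 0.06) were among them. Of 16 late activity response genes, which follow neuronal firing, 9 were lower (12 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.00391; adjusted p = 0.904 with an estimated correlation). Pcsk1 (-0.59, SE 0.06), Homer1 (-0.58, SE 0.08) and Nptx2 (-0.42, SE 0.06) were among them. Of 12 hypoxia response genes 7 were lower and 1 higher, over all genes and adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.0445; adjusted p = 0.280 with an estimated correlation). The kinase gene Pdk1 (-0.65, SE 0.04) and the glucose transporter gene Slc2a1 (-0.52, SE 0.05) were lower. The hypoxia call ended without AKR naive replicate 1 (adjusted p = 0.0556) and without AKR naive replicate 3 (adjusted p = 0.0566).

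H2 genes of antigen presentation and blood genes were lower in naive AKR too. Of 17 genes of MHC and antigen presentation, 11 were lower and 2 higher, over all genes and adjusted over the list alone, with a median of -0.91 (camera adjusted p = 7.65e-07; adjusted p = 0.280 with an estimated correlation). All 10 genes of the H2 complex in the list were among the lower ones, including H2-D1 (-2.45, SE 0.08) and H2-K1 (-1.95, SE 0.10), and because H2 genes vary in sequence between strains and the reference genome is that of C57BL/6, these values are uncertain. Of the other 7 genes of the list 2 were higher and 1 lower, with a median of 0.15, so the group result rests on the H2 genes. Of 5 blood genes 4 were lower, over all genes and adjusted over the list alone (median -0.63, camera adjusted p = 9.34e-06; adjusted p = 0.280 with an estimated correlation). The globin genes Hba-a2 (-5.86, SE 0.23) and Hbb-bs (-0.63, SE 0.12) were lower, and since globin genes come as near-identical copies their single values are uncertain. In the other direction, 8 of 16 pan-GABAergic genes, shared by inhibitory neurons, were higher and none lower (9 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.0202; adjusted p = 0.904 with an estimated correlation). They included Adarb2 (0.86, SE 0.05), a marker of interneurons from the caudal eminence, the developmental factor gene Dlx2 (0.60, SE 0.10), and Slc32a1 (0.30, SE 0.06), the vesicular GABA transporter gene.

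Lists for single interneuron classes did not pass as groups in naive mice. Of 13 somatostatin interneuron genes 4 were higher and 3 lower, over all genes and adjusted over the list alone (median 0.03, camera adjusted p = 0.770). Myh8 was higher by 1.90 (SE 0.16), Crhbp, which encodes a binding protein of the stress peptide CRH, was higher by 0.38 (SE 0.05), and the nitric oxide synthase gene Nos1 was lower at -0.50 (SE 0.07). Of 9 parvalbumin interneuron genes 3 were higher (4 adjusted over the list alone), among them the fast potassium channel gene Kcnc1 (0.20) (camera adjusted p = 0.628). Of 9 VIP interneuron genes 3 were lower, including the serotonin receptor gene Htr3a (-0.88, SE 0.11) and Vip itself (-0.24) (camera adjusted p = 0.553). Of 8 LAMP5 and NDNF interneuron genes 1 was higher, Krt73 (0.78), and 3 were lower, among them Id2 (-0.24) (camera adjusted p = 0.770). The VIP and LAMP5 counts were the same adjusted over the list alone.

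In the naive comparison 6668 of 17645 tested genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 3236 higher and 3432 lower in AKR. Of these, 811 differed by at least 2-fold (345 higher, 466 lower). Of all 17645 tested genes 6127 showed no overlap between the 4 libraries of each strain, against a chance share of 2.86%.

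The second comparison asked the same question in mice taken after OFL. Arnt2 was again higher in AKR, at 549 ± 8.68 CPM (SD, n = 3) against 319 ± 7.77 (SD, n = 3) in B6N, a difference of 0.78 (SE 0.04), or a fold of 1.72 (edgeR adjusted p = 2.6e-11). Sst was at 67.2 ± 2.93 CPM (SD, n = 3) in AKR and 59.8 ± 0.848 in B6N, a difference of 0.17 (SE 0.06) that passed narrowly (edgeR adjusted p = 0.047). The Sst call ended without replicate 1 or 3 of AKR and without replicate 1, 2 or 3 of B6N, that is in 5 of the 6 fits that left out a library, with an adjusted p of up to 0.189, and also with DESeq2 (0.119) and with no count filter (0.0626). Glo1 was higher by 0.92 and Soat1 lower at -0.81 (edgeR adjusted p = 6.2e-09). Cacna1c stood at 187 CPM in AKR and 182 CPM in B6N (log2 0.03, edgeR adjusted p = 0.72), Nrxn3 had a difference of 0.10 (edgeR adjusted p = 0.13) and Nnt -0.04 (edgeR adjusted p = 0.76).

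The genes with the largest differences after OFL included several of the naive ones. Pttg1 was lower in AKR at -6.46, Myo7a at -3.36, Kcnj16 at -3.17 and Etnppl at -2.84. The axonemal dynein genes Dnah6 and Dnah8 were higher by 3.23 and 2.83, the collagen-binding integrin gene Itga11 by 3.06 and Tagap by 3.09. Mpeg1, a macrophage pore-forming protein gene, was lower at -2.61 and Myoc at -2.26.

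Genes of antigen presentation, mainly H2 genes, and blood genes were lower in AKR after OFL as well. Of 12 genes of MHC and antigen presentation 6 were lower and none higher, over all genes and adjusted over the list alone, with a median of -0.50 (camera adjusted p = 2.11e-10; adjusted p = 0.377 with an estimated correlation). H2-D1 (-2.68) and H2-K1 (-2.19) were lowest among the named members, with the limit given for these genes in naive mice. Of the 6 H2 genes 4 were lower (median -1.22), and of the other 6 genes 2 (median -0.25). Of 5 blood genes 4 were lower by both counts (median -0.99, camera adjusted p = 2.11e-10; adjusted p = 0.377 with an estimated correlation). Hba-a2 stood at -5.72 and Hbb-bs at -0.99. Of 12 deep layer neuron genes 6 were lower and 1 higher, over all genes and adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0380; adjusted p = 0.732 with an estimated correlation). Crym (-0.61, SE 0.08), Ccn2 (-0.84, SE 0.12) and the corepressor gene Tle4 (-0.35, SE 0.06) were lower and Pou3f1 (0.55, SE 0.09) was higher. Of 16 pan-GABAergic genes 3 were higher and none lower by both counts, with a median of 0.13 (camera adjusted p = 0.0386; adjusted p = 0.732 with an estimated correlation), including Adarb2 (0.54) and Slc32a1 (0.32). The deep layer call ended without B6N OFL replicate 2 (adjusted p = 0.112), and the pan-GABAergic call ended without AKR OFL replicate 2 (adjusted p = 0.05003) and without B6N OFL replicate 3 (adjusted p = 0.0524).

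Somatostatin interneuron genes did not pass as a group after OFL, with 3 of 12 higher and none lower by both counts (median 0.07, camera adjusted p = 0.410). Myh8 (1.53) and Crhbp (0.54) were higher. Of 25 immediate early genes, induced within minutes of neuronal firing, 4 were lower and none higher (7 lower adjusted over the list alone; median -0.14, camera adjusted p = 0.186). The list passed without AKR OFL replicate 3 (adjusted p = 8.2e-06) and without B6N OFL replicate 3 (0.00386). Npas4, a neuronal bHLH-PAS factor gene induced by calcium influx, was lower at -0.79 (SE 0.19, edgeR adjusted p = 0.0067), a call that ended without B6N OFL replicate 2 (adjusted p = 0.0505), with DESeq2 (0.231) and with all 14 libraries in 1 fit (0.111). Fos was lower at -0.36 (edgeR adjusted p = 0.048), a call that ended without replicate 1 or 2 of AKR and without replicate 1 or 2 of B6N (adjusted p up to 0.252). It also ended with DESeq2 (0.449), all 14 libraries in 1 fit (0.458), upper-quartile factors (0.0547), a filter of 1 CPM (0.0543) and only genes that share no sequence with a pseudogene (0.0637). Of 16 late activity response genes 6 were lower and 2 higher (7 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.151). Pcsk1 (-0.54) and Gadd45g (-0.60) were lower, and the list passed without AKR OFL replicate 2 (adjusted p = 0.0218). Of 16 glucocorticoid response genes 4 were lower and 3 higher (5 lower and 3 higher adjusted over the list alone; median -0.11, camera adjusted p = 0.423). Map3k6 was lower at -1.19 and Plin4 higher by 0.55 (SE 0.12). Of 19 bHLH-PAS factors and ARNT2 partners 4 were higher and 1 lower by both counts (camera adjusted p = 0.151).

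After OFL 2943 of 17994 tested genes passed, 1349 higher and 1594 lower in AKR, and 623 differed by at least 2-fold (270 higher, 353 lower). Of the 17994 tested genes 5570 showed no overlap between the libraries of the strains, against a chance share of 10% with 3 against 3. The count fell to 1934 without B6N OFL replicate 2.

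The strain differences of naive mice and of mice after OFL, measured in separate libraries, shared many genes. Of 15915 genes tested in both, 902 were higher in AKR in both (242 expected by chance) and 1139 lower in both (294 expected), such as Glo1 and Pttg1. Another 56 genes passed in opposite directions, and Plin4 is a named example, at -1.70 in naive mice and 0.55 after OFL. Of the genes called after OFL, 74.2% were called in the same direction in naive mice. Both sets were mapped to the same reference build, so a loss of reads at AKR variants could recur in both. The counts expected by chance do not allow for that. The log2 differences correlated across genes with a Pearson r of 0.839 and a Spearman rho of 0.535, where genes are not independent replicates.

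**Figure D2:**
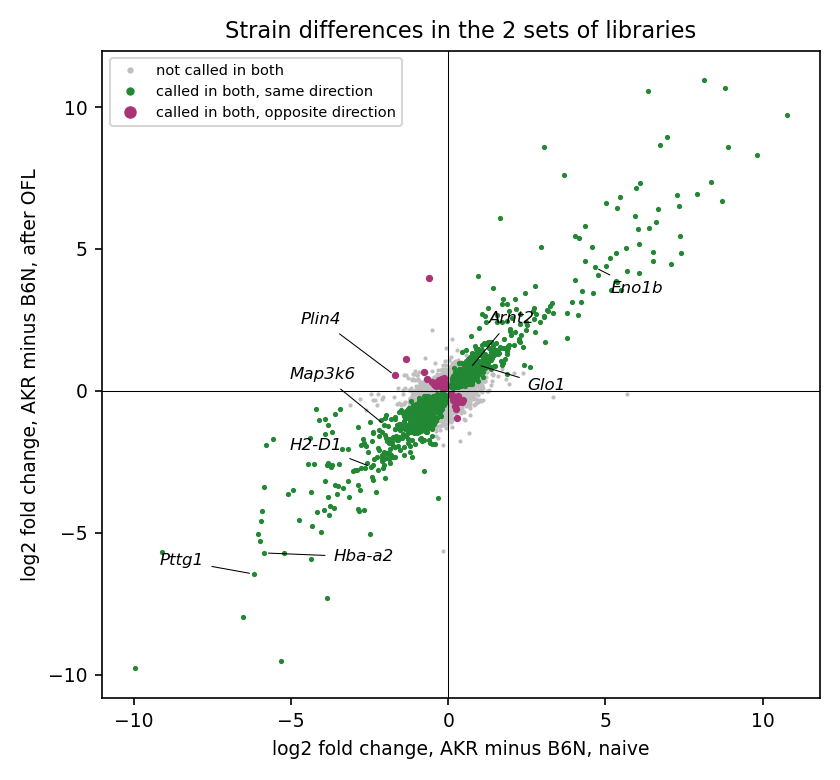
Log2 difference between AKR and B6N of each gene in naive mice (x axis) and after OFL (y axis). Genes called in both with the same direction (2041) lie along the diagonal, and 56 were called in opposite directions.

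**Figure D3:**
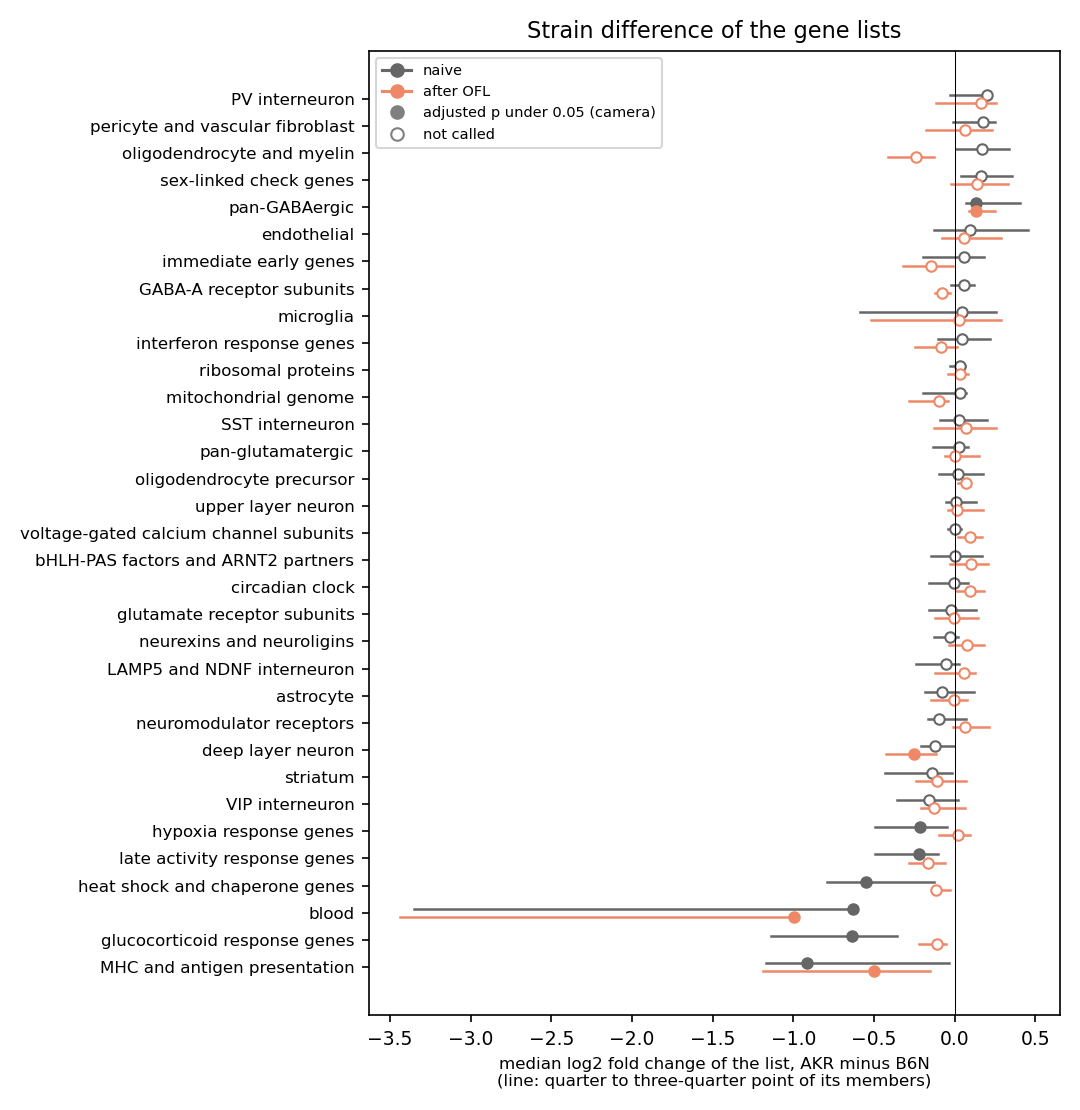
Median log2 difference between AKR and B6N of each gene list with at least 3 tested members, in naive mice and after OFL, with a line over the interquartile range of the members. Filled points passed camera at an adjusted p of 0.05 with the preset correlation: 7 lists in naive mice and 4 after OFL.

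The comparison of OFL with naive libraries within each strain asks what changes after the conditioning, and the sets also differ in the classes of RNA they hold. Sst was lower in the OFL libraries by a log2 difference of -1.29 in AKR and -1.38 in B6N, and Arnt2 was lower at -0.35 and -0.46. Cacna1c was higher by 0.67 and 0.37, while Nrxn3 was higher by 1.13 and 1.04. Arnt2 has exonic bases under an exon of the opposite strand, so its change may also reflect how the sets were counted. Histone genes of the replication-dependent class, whose messages lack a poly(A) tail, had a median of 5.47 in AKR and 4.77 in B6N, with Hist1h4d at 8.66 and 7.67. Small nucleolar RNAs had medians of 4.99 and 5.02, and the nuclear RNA Rn7sk stood at 8.62 and 7.94. The long nuclear RNA Malat1 took 0.10% of the counts in naive AKR and 0.812% in AKR after OFL, and the mitochondrial genome 1.68% and 0.765%. Genes with at least 80% of their exonic bases under exons of the opposite strand (116 genes) had medians of 6.45 and 6.60, against -0.52 and -0.76 for 23 genes covered as much on their own strand.

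**Figure D4:**
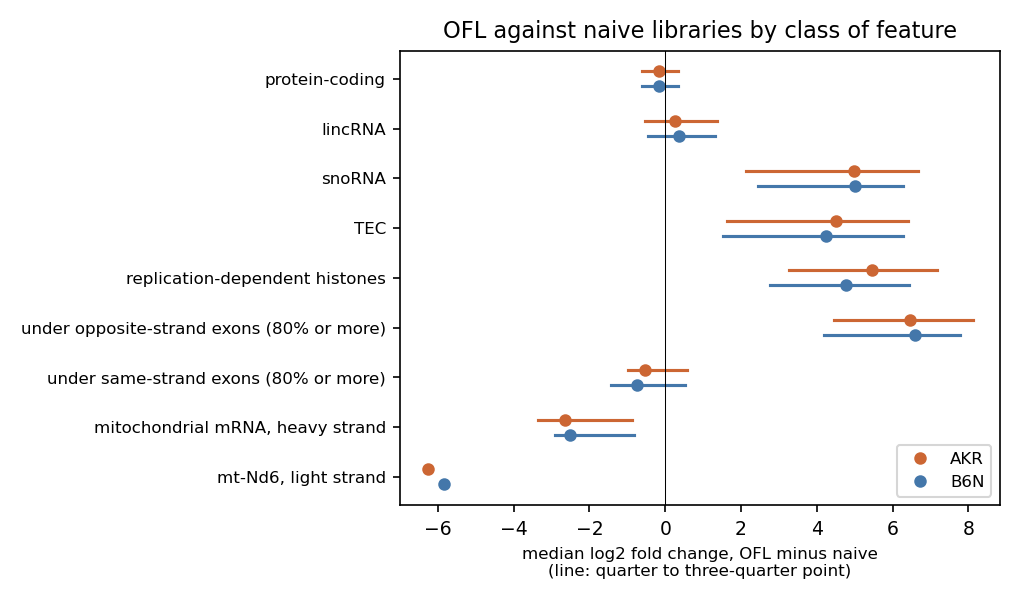
Median log2 difference of OFL minus naive libraries in AKR and B6N by class of feature, with a line over the interquartile range. Histone genes, small nucleolar RNAs and genes under opposite-strand exons lie above 4 in both strains, while protein-coding genes as a whole lie near -0.15.

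Pan-glutamatergic genes and genes of the mitochondrial genome were lower in the OFL libraries of both strains. Of 12 pan-glutamatergic genes 9 fell and 1 rose in AKR (median -0.75, camera adjusted p = 0.00556; adjusted p = 0.278 with an estimated correlation). In B6N 10 fell and 1 rose (median -0.68, adjusted p = 0.00364; adjusted p = 0.356 with an estimated correlation). Nrgn, a postsynaptic calmodulin-binding protein gene, fell by 2.01 on the log2 scale in both strains, and Slc17a7, the vesicular glutamate transporter gene, fell by 0.89 in AKR and 0.90 in B6N. The upper layer (medians -0.03 and 0.01) and deep layer neuron lists (0.17 and 0.24) did not pass in either strain. Of 18 genes of the mitochondrial genome 12 fell and 5 rose in each strain (medians -1.83 and -1.85, camera adjusted p = 7.24e-10 and 5.15e-09; adjusted p = 0.278 and 0.356 with an estimated correlation). The respiratory complex genes mt-Nd2 (-4.25 and -4.11) and mt-Nd4 (-3.18 and -2.96) were among those that fell. Of 22 glutamate receptor subunit genes 14 rose and 6 fell in AKR (median 0.39, camera adjusted p = 0.0236; adjusted p = 0.278 with an estimated correlation). In B6N 13 rose and 7 fell (median 0.34, adjusted p = 0.0343; adjusted p = 0.356 with an estimated correlation). Grin2a rose by 1.94 in AKR and 1.75 in B6N, and Grin2b by 1.92 and 1.53. Adjusted over the list alone, the counts of these lists were the same except for 7 glutamate receptor genes that fell in AKR. The glutamate receptor call ended in B6N without B6N naive replicate 3 (adjusted p = 0.0539), and in both strains with a replicate block (adjusted p = 0.0812 in AKR and 0.107 in B6N).

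Somatostatin interneuron and ribosomal protein genes were also lower as groups. Of 13 somatostatin interneuron genes 9 fell and 1 rose in each strain, over all genes and adjusted over the list alone (medians -0.70 in AKR and -0.71 in B6N; camera adjusted p = 0.0480 and 0.0343; adjusted p = 0.278 and 0.356 with an estimated correlation). They included Elfn1 (-1.39 and -1.62), a synaptic organizer gene of these cells, and Npy (-0.72 and -0.71). Other cell type lists fell by similar amounts without passing: pan-GABAergic (medians -0.66 and -0.65, camera adjusted p = 0.131 and 0.185), PV interneuron (-0.61 and -0.46, 0.232 and 0.218) and microglia genes (-0.59 and -0.57, 0.131 and 0.0938). Of 76 ribosomal protein genes 49 fell and 9 rose in AKR and 50 fell and 7 rose in B6N by both counts (median -0.22 in each; camera adjusted p = 0.0480 and 0.0343; adjusted p = 0.930 and 0.818 with an estimated correlation). Rps16 stood at -2.04 and -2.13 and, in the other direction, Rpl23a at 3.19 and 3.29. The somatostatin call in AKR ended without AKR naive replicate 1 (adjusted p = 0.0642), AKR naive replicate 2 (0.0666) and AKR OFL replicate 1 (0.0665). The ribosomal call in AKR ended without the same libraries (adjusted p = 0.0797, 0.0865 and 0.0665), and in B6N without B6N OFL replicate 1 (0.0726). With any of those 3 AKR libraries left out, 3 lists passed in AKR in place of 5.

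Immediate early genes did not pass as a group in either strain. In AKR 10 of 25 fell and 3 rose (camera adjusted p = 0.352). In B6N 9 fell and 6 rose (adjusted p = 0.377), with the same counts adjusted over the list alone. Egr1, a zinc finger factor gene induced by neuronal activity, was at -1.15 in AKR and -1.11 in B6N, and Egr3 at -0.84 and -1.21. Homer1, encoding a postsynaptic scaffold, was higher by 1.53 and 1.02, and the adhesion gene Nlgn1 by 1.70 and 1.78.

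In AKR 15968 of 20291 tested genes passed (78.7%; 8085 higher and 7883 lower in OFL), and in B6N 15916 passed (78.4%; 8118 higher and 7798 lower). The protein-coding genes among them leaned the other way, with 4729 higher and 6926 lower in AKR and 4742 and 6873 in B6N. With quantile normalization 42.7% and 43.3% of the genes called were higher. Of the 20291 genes 7421 were higher after OFL in both strains, 6918 lower in both and 82 called in opposite directions. Several genes had no count in a group: Snora73b was at least 525-fold higher after OFL in AKR and 523-fold in B6N, the protocadherin gene Pcdhga10 at least 366-fold and 427-fold, and Il4 at least 126-fold lower in AKR, against a floor of 3 counts over the group that covers counting error only. Large changes were also seen in genes under opposite-strand exons. These folds may therefore reflect how the sets were counted, and they do not show that a gene was switched on or off. Because condition and set of libraries coincide, no value here separates the conditioning from how the sets were made.

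The strain by condition interaction asks whether the OFL minus naive difference is larger in AKR than in B6N, so that a shift shared by both strains drops out of it. A difference between the sets of libraries that acts unlike in the strains, for instance at strain variants, does not drop out. Glucocorticoid response genes differed most clearly: 7 of 17 had a higher change in AKR and none a lower one (11 and none adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.15e-20), and the call held with an estimated correlation (adjusted p = 0.0196). Tsc22d3 (1.11, SE 0.09), Fkbp5 (0.95, SE 0.12) and Plin4 (2.26, SE 0.20) were among the 7. Within strains, 12 of the 17 fell and 4 rose in B6N (median -0.87, camera adjusted p = 0.0624), and 6 fell and 7 rose in AKR (median -0.16, adjusted p = 0.922), with the same counts adjusted over the list alone. In B6N the list passed without naive replicate 1 (adjusted p = 0.0471), naive replicate 4 (0.0360) or OFL replicate 3 (0.0425). Arnt2 had an interaction of 0.11 (SE 0.05, edgeR adjusted p = 0.23) and Sst 0.10 (edgeR adjusted p = 0.48), neither past the test, and Nrxn3 did not pass either (edgeR adjusted p = 0.45). Cacna1c passed with 0.31 (SE 0.07, edgeR adjusted p = 0.0094).

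Single genes with large interactions were the microtubule-associated ubiquitin ligase gene Mid1 (2.81, SE 0.28, edgeR adjusted p = 2.5e-07) and H2-T24 (2.45, SE 0.18, edgeR adjusted p = 8.0e-10). The value of H2-T24 has the limit given for H2 genes in naive mice. The small GTPase gene Rasd1, induced by dexamethasone, stood at 1.54 and the chaperone partner gene Sdf2l1 at 1.21. In the other direction stood Opalin (-1.12), a myelin gene, and Lmbr1 (-1.11). Vcp-rs (-1.61) and Rps3a2 (-1.46) also had lower changes in AKR, with the uncertainty of copied genes, and the Rps3a2 call ended with quantile normalization (-0.66, adjusted p = 0.277).

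Several other lists passed the interaction with the preset correlation but not with an estimated one. With fry the calls of 4 lists given here and below ended: heat shock (fry adjusted p = 0.0736), oligodendrocyte and myelin (0.338), late activity (0.217) and GABA-A receptor genes (0.0696). Of 11 heat shock genes 3 had a higher change in AKR (6 adjusted over the list alone; median 0.24, camera adjusted p = 8.1e-06; adjusted p = 0.313 with an estimated correlation). Hspa5 (0.86, SE 0.13) and Hsph1 (0.44, SE 0.08) were among them. Of 12 hypoxia response genes 2 did by both counts, Slc2a1 (0.58, SE 0.07) and P4ha1 (0.49) (median 0.22, camera adjusted p = 0.00347; adjusted p = 0.0743 with an estimated correlation). Of 15 voltage-gated calcium channel genes 3 did by both counts, among them Cacna1c and Cacna1i (0.26) (median 0.12, camera adjusted p = 0.000995; adjusted p = 0.253 with an estimated correlation). Of 12 oligodendrocyte and myelin genes 3 had a lower change in AKR (4 adjusted over the list alone; median -0.34, camera adjusted p = 2.68e-05; adjusted p = 0.553 with an estimated correlation). Among the 3, Aspa lost its call with DESeq2 (adjusted p = 0.0882). Ugt8a lost its call with DESeq2 (adjusted p = 0.127), quantile normalization (0.0616), genes clear of opposite-strand exons (0.0630) and thinned naive libraries (0.0702).

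Each of the other 5 lists that passed lost its call without at least 1 library. Of 16 late activity genes 3 had a higher change in AKR (5 adjusted over the list alone; median 0.15, camera adjusted p = 0.00570; adjusted p = 0.617 with an estimated correlation). They were Inhba (0.83, SE 0.15), Homer1 (0.51, SE 0.11) and Mapk4 (0.35, SE 0.07). The call ended without AKR naive replicate 4 (adjusted p = 0.0799) and AKR OFL replicate 2 (0.0551). Of 12 GABA-A receptor genes 1 had a lower change (2 adjusted over the list alone; median -0.13, camera adjusted p = 0.0144; adjusted p = 0.313 with an estimated correlation). The call ended without B6N OFL replicate 3 (adjusted p = 0.0818). Of 13 neurexin and neuroligin genes 1 had a higher change (5 adjusted over the list alone; median 0.15, camera adjusted p = 0.0233; adjusted p = 0.168 with an estimated correlation). It ended without AKR naive replicate 1 (adjusted p = 0.0518). Of 17 clock genes 4 had a higher and 1 a lower change (6 and 3 adjusted over the list alone; median 0.07, camera adjusted p = 0.0250; adjusted p = 0.253 with an estimated correlation). Per2 stood at 0.66 (SE 0.08) and Cry1 at 0.46. The clock call ended without AKR naive replicate 4 (adjusted p = 0.0799), AKR OFL replicate 3 (0.0642) and B6N OFL replicate 3 (0.0928). Of 19 bHLH-PAS factors and ARNT2 partners 3 had a higher and 1 a lower change (4 and 1 adjusted over the list alone; median 0.07, camera adjusted p = 0.0370; adjusted p = 0.313 with an estimated correlation). The hypoxia factor gene Hif3a stood at 0.84 (SE 0.13) and Npas3 at -0.55. That call ended without replicate 4 of naive AKR (adjusted p = 0.105), replicate 1 of naive B6N (0.0575), replicates 1 and 3 of AKR OFL (0.0792 and 0.0642) and replicate 3 of B6N OFL (0.0944).

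Across all genes 1044 of 20291 passed the interaction, 732 with a higher and 312 with a lower change in AKR, and 198 by at least 2-fold.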

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

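In this part the thinning of the naive libraries and the tests of opposite-strand exons, histone genes, the strain variant, vascular markers and pseudogene parents were chosen only after the results were seen.

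Most genes differed between OFL and naive libraries: 15241 genes passed with the 7 AKR libraries alone and 15440 with the 7 B6N libraries alone. In each strain 1 of 35 splits, the real one, called as many (highest other 0), which argues against a chance split of these libraries. Chance differences between animals were not tested, since the labels do not say that the libraries came from separate animals. Depth is argued against, since 78.3% of the genes tested in AKR still passed after the naive counts were thinned to the OFL depth. The pattern may in part come from how the sets of libraries were made: genes under opposite-strand exons had a median log2 change of 6.45 in AKR, which suggests counting by strand in the OFL set alone, since counting without strand drops reads under 2 genes, and histone genes, which lack poly(A) tails, had a median of 5.47, which suggests that RNA without such tails was kept in the OFL set. These classes are not the whole pattern, since of the protein-coding genes outside both classes 77.0% passed in B6N, the lower share of the strains. That share cannot exclude the library differences as the whole cause, since they may also move genes outside both classes. What stays open for those genes is the conditioning itself, the time or batch of sampling, or a wider effect of library type, and the design does not separate them.

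Glucocorticoid response genes were lower in naive AKR (15 of 17). The strain difference of the list was smaller after OFL, with a median interaction of 0.42 (0.419, camera adjusted p = 0.0196 with an estimated correlation). This tested the difference between the sets of libraries directly, but condition and set coincide. If both sets were made and counted alike, a strain variant that lowers mapping to the reference would give the same strain difference in each. That interaction argues against such a variant for the list as a whole under this condition. Since the sets differ in the RNA they hold, the test cannot exclude a variant. A single library is argued against too, since at least 15 members were lower in AKR in each of the 8 fits that left out a library. Fewer vascular cells, which express several of these genes, is argued against as the source by the endothelial, pericyte and vascular fibroblast markers, of which 6 of 18 were higher in AKR and 4 lower. A difference in stress hormone exposure between the naive groups, or in the response to it, is a candidate explanation that no value here tests.

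More processed pseudogenes were higher than lower in AKR, 66 against 23 of 310 in naive libraries (3236 against 3432 over all 17645 genes) and 45 against 17 of 434 after OFL, and a candidate explanation is that reads of a parent gene that differ from the reference in AKR are assigned to its copy. In naive libraries 60.0% of the 50 parents of copies at least 2-fold higher in AKR were themselves lower, against 13.8% of 123 parents of copies that were not called (Fisher's exact test, two-sided p = 2.6e-09). In OFL libraries the shares were 63.9% of 36 and 11.5% of 148 (Fisher's exact test, two-sided p = 4.3e-10). In OFL libraries Hspa8 was such a parent, and no biological explanation was tested. In naive libraries the higher copies gained 848.7 CPM together, while their parents lost a net 643.5 CPM. After OFL the copies gained 559.3 CPM and their parents lost a net 1237 CPM, so gains and losses did not balance. The parents compared were not matched by level, which also bears on how readily a gene is called.

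In the naive strain comparison 1 of 35 splits called as many genes as the real 6668 (highest other 0). This argues against a chance split of these libraries, but chance differences between animals were not tested. After OFL the 10 splits are too few for a share under 0.05, with 2943 genes in the real split and 0 in the highest other. For the interaction 2 of 90 splits called at least the real 1044, the real one included. The highest other, 1505, exchanged the strains in all OFL libraries, which keeps the OFL strain difference with its sign turned. How that split labelled the naive libraries was not recorded. Splits that mix the strains within a condition weaken the strain difference there along with any interaction. The splits therefore cannot decide whether the interaction arose by chance.

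A library stood apart from the other 3 of its group in 5 of 104 groups of values tested, where chance gives about 1 in 20. In AKR naive replicate 1 the mean log2 CPM was lowest for deep layer neuron genes (3.80, nearest 4.23) and striatum genes (3.29, nearest 3.48) and highest for astrocyte genes (7.26, nearest 7.10). In B6N naive replicate 2 it was highest for oligodendrocyte genes (6.22, nearest 5.72) and for pericyte and vascular fibroblast genes (3.95, nearest 3.83).

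Over all genes 1044 of 20291 (5.1%) passed the interaction test, and choosing genes by a large strain difference in 1 set of libraries favors an interaction. By this test the strain difference changed between naive and OFL libraries for 10 of 37 genes, those named in advance or for the size of their strain difference, with members of gene lists aside. It was higher after OFL for Cacna1c by 0.31 (edgeR adjusted p = 0.0094), Dnah6 by 1.11 (0.0075), Fam205c by 6.27 (2.96e-05), Fcrls by 0.69 (0.0123), Itga11 by 1.197 (0.0064) and Mid1 by 2.81 (2.5e-07). It was lower after OFL for Myoc at -0.84 (edgeR adjusted p = 0.0167), Pcdhgb8 at -0.83 (0.0134), Rps3a2 at -1.46 (0.0017, but -0.66 and 0.277 with quantile normalization) and Vcp-rs at -1.61 (6.5e-07).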

How the results depend on the processing

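Of the alternatives, the recovered reads, the genes that share no sequence with a pseudogene or lie clear of opposite-strand exons, and the thinned libraries were chosen after seeing the data. No named gene or list that was called changed direction under an alternative, but values near 0 that were not called did, such as Cacna1c after OFL (-0.01 to 0.08 with a library left out). Of all genes called, 9 changed direction in AKR among genes clear of opposite-strand exons and 2 in B6N with quantile normalization. The counts of genes stayed within 1.5 times under other scalings, filters, DESeq2 (5760 naive, 2153 after OFL, 15319 and 15296 for OFL minus naive in AKR and B6N, 1020 for the interaction), limma-voom, the replicate block and the recovered reads. Testing against a fold of 1.5 left 851, 505, 8269, 8304 and 64 genes, by its own construction. Among protein-coding genes clear of opposite-strand exons, 7745 passed in AKR and 7792 in B6N, since fewer genes were tested. The log2 changes of these genes also stood above those of the main fit, by a median of 0.180 in AKR and 0.155 in B6N. Small OFL minus naive changes, such as the median of the ribosomal protein genes, therefore depend on which genes set the scale. Leaving out a library gave 5680 to 6747 genes in naive mice, 1934 to 3514 after OFL, 15551 to 15835 in AKR, 15511 to 15713 in B6N and 732 to 1273 for the interaction. The number of lists that passed then ranged from 6 to 8, 3 to 6, 3 to 5, 4 to 6 and 8 to 10 in the same order. With a correlation estimated from the data, camera passed 0 lists in naive mice, after OFL, in AKR and in B6N and 1 for the interaction, with 4, 2, 5, 4 and 5 at an unadjusted p under 0.05 in the same order. fry, which does not compare a list with other genes, passed 10 lists in naive mice, 9 after OFL, 24 in AKR, 25 in B6N and 6 for the interaction, and its mixed test 32, 29, 32, 33 and 17 over the 5 comparisons. Genes called in the same direction in naive mice and after OFL numbered 1337 at an adjusted p of 0.01 in each, as a stricter threshold must lower it. The comparison of the count tables with counts per sample was not run, since the sample tables hold CPM. Of the named genes called, 134 of 145 in naive mice, 84 of 123 after OFL, 147 of 153 in AKR, 151 of 152 in B6N and 47 of 65 for the interaction kept their call with each library left out in turn. At these depths and sample numbers 76.1% of simulated 1.5-fold changes were recovered for the interaction, and thinning the naive libraries to the OFL depth left 938 genes there.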

Other observations

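The test of clock genes in this part was chosen only after the result was seen.

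Microglial genes moved apart between the strains in naive mice. Of 12 tested, 4 were higher and 5 lower in AKR, over all genes and adjusted over the list alone, with a median of 0.05 and a mean of -0.09 (camera adjusted p = 0.480, tested as lower). The complement genes C1qb (-1.38, SE 0.06), C1qc (-1.21, SE 0.06) and C1qa (-0.76, SE 0.05) were lower, while Aif1, encoding the microglial calcium-binding protein Iba1, was higher by 1.35 (SE 0.09). After OFL C1qb (-1.18), C1qc (-1.13) and C1qa (-0.63) were again lower, and the purinergic receptor gene P2ry12 was higher by 0.66. Of 10 endothelial genes 4 were higher and 2 lower in naive AKR (4 and 3 adjusted over the list alone; camera adjusted p = 0.613), with the receptor gene Kdr higher by 0.74 (SE 0.08) and Ly6c1 lower at -0.63. Of 8 pericyte and vascular fibroblast genes 2 were higher and 2 lower by both counts (camera adjusted p = 0.724). Of 12 oligodendrocyte and myelin genes 5 were higher and 2 lower by both counts (camera adjusted p = 0.628), with Ugt8a higher by 0.39 and Mobp lower at -0.37, and the list passed without B6N naive replicate 2 (adjusted p = 0.0119). Of 8 precursor genes 2 were higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.958), among them Gpr17 at -0.34. Of 12 astrocyte genes 3 were higher and 4 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.770), with the serine transporter gene Slc7a10 higher by 0.41 and the connexin gene Gjb6 lower at -0.57.

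Receptor genes also differed one by one in naive mice. Of 18 neuromodulator receptor genes 2 were higher and 5 lower in AKR by both counts (camera adjusted p = 0.770): the serotonin receptor gene Htr1a was higher by 0.56 (SE 0.07), Htr1b lower at -1.11 (SE 0.11) and the kappa opioid receptor gene Oprk1 lower at -0.82. Of 22 glutamate receptor genes 6 were higher and 6 lower by both counts (camera adjusted p = 0.770), with Grm2 higher by 0.51 (SE 0.04) and Grin2b lower at -0.74 (SE 0.04). Of 12 GABA-A receptor genes 4 were higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.770). Of 15 calcium channel genes 2 were lower by both counts (Cacna1c and Cacna1e, the latter at -0.28; camera adjusted p = 0.777), and the list had a median of 0.00 and a mean of -0.03. Of 13 neurexin and neuroligin genes 2 were higher and 4 lower by both counts (camera adjusted p = 0.770), with Nlgn2 higher by 0.18.

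The other lists did not pass in naive mice. Of 12 pan-glutamatergic genes 2 were higher and 3 lower by both counts (camera adjusted p = 0.777), and of 13 deep layer genes 1 was higher and 3 lower by both counts (0.770). Of 11 upper layer genes 4 were higher and 3 lower by both counts (camera adjusted p = 0.777, tested as higher), with a median of 0.00 and a mean of -0.05. Of 25 immediate early genes 5 were lower and none higher (4 adjusted over the list alone; median 0.06, mean -0.04, camera adjusted p = 0.770, tested as lower), with Maff at -1.27 (SE 0.22). Of 19 bHLH-PAS factors and ARNT2 partners 4 were higher and 6 lower by both counts, with a median just under 0, a mean of 0.05 and a camera adjusted p of 0.770 (tested as higher). Beside Arnt2, Npas1 was higher by 0.60 and Npas3 by 0.67. Of 8 striatum genes 3 were lower by both counts (camera adjusted p = 0.553), and of 16 interferon response genes 1 was lower by both counts, the antiviral gene Ifitm3 (median 0.04, mean -0.01, camera adjusted p = 0.946). Of 74 ribosomal protein genes 8 were higher and 12 lower (7 and 12 adjusted over the list alone; median 0.03, mean -0.06, camera adjusted p = 0.553). Of 15 mitochondrial genes 2 were higher and 5 lower by both counts (median 0.03, mean -0.03, camera adjusted p = 0.770). Xist, expressed from the inactive X chromosome of females, had 0 to 6 counts per library in all 14 libraries, and the Y-linked gene Ddx3y 1178 to 1547. Of 4 Y-linked genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.392). Of the choroid plexus list 2 members passed the filter, too few for a list test, and neither was called.

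Of 17 clock genes 3 were higher and 6 lower in naive AKR by both counts (camera adjusted p = 0.958), among them Dbp (0.54) and Nr1d1 (0.38) higher and Arntl (-0.40) and Per2 (-0.35) lower. A hypothesis is that tissue of the strains was taken at different clock phases, in which genes driven by E-boxes and D-boxes and genes driven by ROR elements may move apart. Their mean log2 differences were 0.11 for 10 genes and -0.21 for 5 genes, 0.326 apart (exact permutation test across genes, two-sided, p = 0.0376), and 0.236 apart after OFL (p = 0.0566 in the same exact permutation test). In naive mice the 10 genes were split, with 3 called higher and 2 lower, while 4 of the 5 were lower and none higher. Genes are not independent replicates, the labels give no collection time, and a strain difference in clock genes at the same phase stays open.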
